A study of Arabidopsis thaliana with 6 samples.

How the data were processed

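Total RNA including the small fraction had been isolated with the mirVana kit, and TruSeq small RNA libraries had been sequenced on an Illumina GAIIx, per the labels' protocols. The authors deposited 1 table with raw read counts of 294 mature miRNA sequences of 19 to 24 nt in 6 libraries. Per the file headers, these counts are of reads that match the annotated mature sequence exactly, grouped by mature sequence, so reads with a trimmed, extended or edited end are not in them and identical sequences from several loci share a row. The submitters' processing notes name TAIR10 as the genome build, and the trimming, aligner and miRNA database version are not given in the sources used here. Exact matching means that a plant variant or a sequencing error removes a read from its row and can add it to that of a 1-base neighbour. The bri1-5 mutant is not in the background of the reference accession, and no variant was looked for. No adapter, molecular identifier or length filter is stated, so PCR copies count as reads.

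The same deposited table holds the authors' own comparison. Its p-value comes from a test whose column header names an EDGE test with tagwise dispersions, per the file headers, and it is not adjusted. The signed fold and the log2 fold change in the table are the authors', epiBL over control, and the log2 column equals the log2 of the fold. Per the file headers the comparison is between 0 min and 90 min, whereas the labels give 90 min for both groups, with solvent or 1 µM epiBL. The groups here follow the labels, and the counts behind the columns named control and BL are those compared.

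The counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. miRNAs were kept by edgeR's filterByExpr with its default minimum count of 10 and total of 15, which left 148. Counts were scaled by TMM factors and tested with edgeR's quasi-likelihood F test (robust fit), adjusted by Benjamini-Hochberg, with a threshold of 0.05. Normalised counts are CPM of the TMM-scaled total, as edgeR's cpm function gives them. A standard error is the log2 fold change divided by the square root of F. The biological coefficient of variation was 10.9%. No replicate pairing was used. The replicates are labelled as biological, without saying whether they came from separate cultures, so p-values measure the spread between these samples. No pair of libraries agreed within sampling noise.

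A set of 10 miRNA lists was written by family number before the data were examined, as were the tests, the rule for named miRNAs and most alternatives. Lists were tested with camera at a preset correlation of 0.01, with adjustment over the 10 lists, and again with an estimated correlation and with fry. Arm ratios were log2 ratios of counts plus 0.5, tested with limma. Shares and totals were compared with two-sided exact permutation tests. The miRNAs named are those with an adjusted p under 0.05, the 6 with the smallest p in each direction, the member of each list with the smallest p and that with the highest mean, and the 5 most abundant. miR156a-f-5p, miR398a-3p, miR857-3p and the neighbours named later were chosen after their values were seen. The 294 sequences were matched exactly to the TAIR10.1 assembly, and all 294 had a match in an annotated precursor, 215 of them a single match. Coordinates are from that match, counted from 1.

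The procedure was tested on simulated counts of 148 miRNAs, a part of them changed, over 20 simulations. Pooled over these, 240 miRNAs were changed at each size and 2240 were unchanged. More were changed per simulation than were called in the data, which can raise recovery, and dispersion was set by abundance alone. For epiBL against control, it recovered 70% of miRNAs changed 1.5-fold, 90% of those changed 2-fold and 97.1% of those changed 4-fold, and called 1.5% of unchanged ones. Camera called a copper-responsive list set to 0.75 of control in 100% of simulations and 0.714% of unchanged lists. Counts were drawn independently for each miRNA, so these rates do not cover lists with correlated members. For arm ratios at 45 pairs, limma called 93.1% of those changed at least 2-fold and 2.8% of unchanged ones. Alternatives were a replicate block, DESeq2, other scalings and filters, limma-trend, sums per family, other thresholds and leaving out each library. Removal of a trend with GC content, thinning to the shallowest library, total-count scaling for the lists and leaving out libraries for the totals were chosen after seeing the data.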

Results

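Small RNA was sequenced from Arabidopsis thaliana seedlings grown in shaking liquid culture and harvested 90 min after addition of 1 µM epibrassinolide (epiBL, an active brassinosteroid, the class of plant steroid hormones that promotes cell elongation) or of the solvent alone. The plants carried a Flag-tagged copy of BRI1, the plasma-membrane receptor of brassinosteroids, in the bri1-5 receptor mutant. Each group held 3 biological replicates, so there were 6 libraries. The comparison asks which microRNAs (miRNAs), the short RNAs that guide cleavage or repression of matching mRNAs, respond to the hormone. Reads identical to an annotated mature miRNA summed to 4482479, 3878714 and 3931715 in control replicates 1, 2 and 3, and to 3732417, 4112329 and 2050074 in epiBL replicates 1, 2 and 3. Of 294 mature sequences listed, 257 had a read in at least 1 library. In the shallowest library, epiBL replicate 3, 3 counts corresponded to 1.46 CPM (counts scaled to the library total), so a miRNA without a read there was below that level, for counting error only.

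miR166a-g-3p, which targets the class of homeodomain-leucine zipper transcription factors that pattern leaves and meristems, was the most abundant miRNA in all 6 libraries. It took 41.8% ± 0.963 (SD, n = 3) of the counts in controls and 44.3% ± 2.60 (SD, n = 3) with epiBL. The difference was not distinguishable from the replicate spread (two-sided exact permutation test, p = 0.3, where 3 against 3 libraries cannot go below 0.1). The 5 most abundant miRNAs together took 84.8% ± 0.602 (SD, n = 3) in controls and 86.2% ± 0.977 (SD, n = 3) with epiBL (exact permutation p = 0.2). Total counts did not separate the groups either (exact permutation p = 0.4). Normalised counts (CPM) of the other leading miRNAs, miR158a-3p, miR165a/b-3p, miR398b/c-3p and miR159a-3p, had log2 fold changes of 0.08 (SE 0.12), 0.25 (SE 0.12), -0.02 (SE 0.10) and 0.00 (SE 0.12), and none passed the test.

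After 90 min of epiBL, 12 of the 148 miRNAs tested differed from the solvent control, 4 of them higher and 8 lower. The largest change was that of miR156g-5p, a minor member of the family that restrains SPL transcription factors and so delays the change from juvenile to adult growth. It rose 4.01-fold, from 7.92 ± 1.24 to 32.2 ± 3.75 CPM (normalised counts, SD, n = 3 each). miR398a-5p, the passenger arm of a precursor whose other arm targets copper/zinc superoxide dismutases, dropped to 0.465 of its control level, from 71.5 ± 11.6 to 33.7 ± 3.30 CPM (SD, n = 3 each). miR397a-5p, which targets laccases, dropped from 113 ± 3.24 to 67.2 ± 2.52 CPM (SD, n = 3 each). miR395a/d/e-3p, which targets ATP sulfurylases and a sulfate transporter, rose from 88.6 ± 7.33 to 141 ± 5.22 CPM (SD, n = 3 each).

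**Figure D1:**
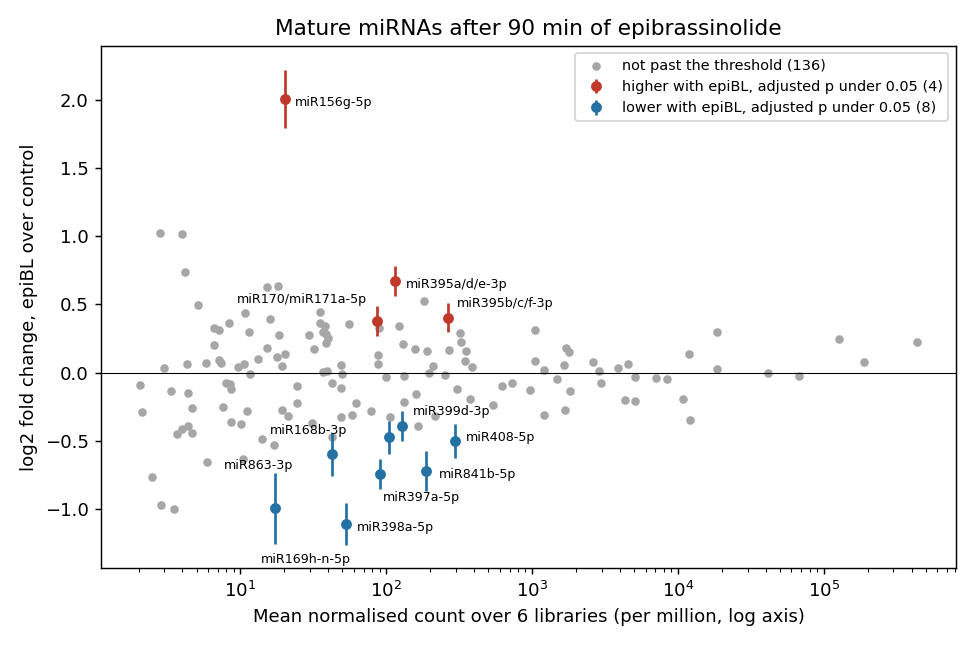
Each point is 1 of 148 tested miRNAs, with its mean normalised count over 6 libraries (CPM, log axis) against its log2 fold change of epiBL over control. Coloured points are the 4 higher and 8 lower miRNAs past an adjusted p of 0.05, with whiskers of 1 standard error, and miR156g-5p stands apart at 2.00.

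In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change of miR156g-5p was 2.00 (SE 0.22, adjusted p = 2.4e-05), that of miR398a-5p -1.11 (SE 0.15, adjusted p = 0.000237), that of miR397a-5p -0.74 (SE 0.11, adjusted p = 0.000358) and that of miR395a/d/e-3p 0.67 (SE 0.11, adjusted p = 0.000876). The other miRNAs that rose were miR395b/c/f-3p (0.40, SE 0.11) and miR170/miR171a-5p (0.38, SE 0.11), the latter the passenger arm of precursors whose 3p arms target GRAS-domain regulators of meristems. The others that fell were miR841b-5p (-0.72, SE 0.14), miR169h-n-5p (-0.99, SE 0.26), of a family that targets NF-YA transcription factors, miR863-3p (-0.60, SE 0.16), miR408-5p (-0.50, SE 0.13), miR168b-3p (-0.47, SE 0.12), the 3p arm of a precursor whose 5p arm targets ARGONAUTE1, and miR399d-3p (-0.39, SE 0.11), of a family that targets the phosphate regulator PHO2. Their adjusted p ran from 0.00572 for miR841b-5p to 0.0403 for miR170/miR171a-5p. In all 12 the 3 epiBL libraries lay wholly above or below the 3 control libraries, as they did in 27.7% of the tested miRNAs, where chance gives 10%. miR156g-5p differs from the far more abundant miR156a-f-5p by 1 base (T1C, miR156a-f-5p first, counted from 1 at the 5′ end), and its counts were 0.208% ± 0.0151 of that neighbour's in controls and 0.820% ± 0.0838 with epiBL (SD, n = 3 each). miR156a-f-5p itself had a log2 fold change of 0.04 (SE 0.12) and did not pass.

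**Figure D2:**
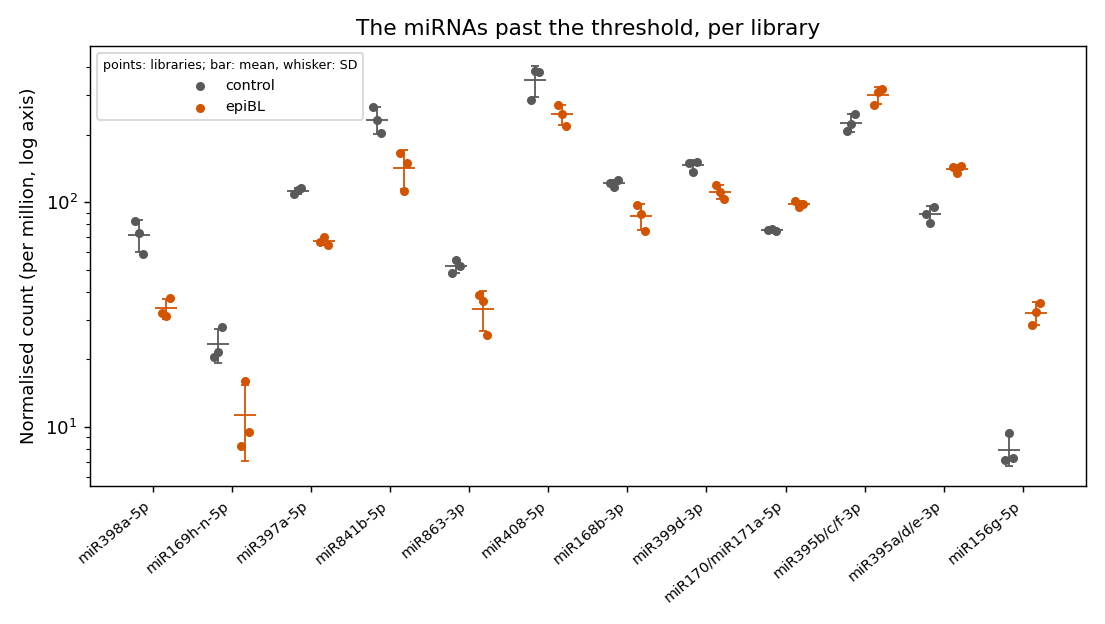
Normalised counts (CPM, log axis) of the 12 miRNAs past the threshold, ordered by fold change. Points are libraries, horizontal bars the mean of 3 and whiskers the SD, and control and epiBL points do not overlap for any of the 12.

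Among the 12, miR156g-5p, miR398a-5p, miR397a-5p, miR395a/d/e-3p and miR841b-5p passed whichever library was left out, and the other 7 each passed in only 1 to 3 of the 6 such fits. The count was 5 without control replicate 2 or without epiBL replicate 3, 7 without control replicate 3 and 25 without epiBL replicate 2, and scaling by total counts alone gave 2 higher and 15 lower, with the median of all miRNAs at -0.13.

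The sequence of miR156g-5p lies on chromosome 2 at 8412589-8412608 of the TAIR10.1 assembly, minus strand, in the MIR156g precursor, within an intron of AT2G19420 on the opposite strand. miR398a-5p lies on chromosome 2 at 1040948-1040968, plus strand, in MIR398a and outside any protein-coding gene. miR397a-5p lies on chromosome 4 at 2625960-2625980, plus strand, opposite an intron of AT4G05110, and miR408-5p on chromosome 2 at 19319866-19319886, plus strand, opposite a UTR exon of AT2G47020. miR841b-5p (chromosome 4, 2184325-2184345, plus strand), miR863-3p (chromosome 4, 7846835-7846855, plus strand), miR168b-3p (chromosome 5, 18358803-18358823, minus strand) and miR399d-3p (chromosome 2, 14442988-14443008, minus strand) lie outside protein-coding genes. miR395a/d/e-3p and miR395b/c/f-3p each match 3 loci on chromosome 1, and the first match of each starts at 9363206 and 9364540. miR169h-n-5p matches MIR169h on chromosome 1 at 6695544-6695564 and a run of 6 further precursors on chromosome 3 from 9872106 to 9878710. miR170/miR171a-5p matches MIR171a on chromosome 3 at 19073452-19073472 and MIR170 on chromosome 5 at 26411635-26411655. Reads of miRNAs with several identical loci cannot be assigned to one of them.

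Of 9 measured sequences of copper-responsive families, whose guide strands lower copper proteins when copper is scarce, 3 fell, none rose and 6 did not pass. Those that fell were miR398a-5p, miR397a-5p and miR408-5p. Of them, miR398a-5p is taken as a passenger arm, though its mean of 52.6 CPM was above the 19.4 CPM counted as miR398a-3p. miR408-5p (mean 298 CPM) was the scarcer arm of its precursor. The other arm, miR408-3p (mean 4314 CPM), had a log2 fold change of -0.20 (SE 0.10) and did not pass. The list was lower than the other miRNAs in camera with a preset correlation (adjusted p = 0.0013), but not with an estimated correlation (adjusted p = 0.153) or with 1 value per family (adjusted p = 0.158). The estimated correlation, 0.000865, was below the preset 0.01, so allowing for correlated members did not remove the call. The family values are 4 sums, in which the 3 sequences that fell weigh little beside more abundant members. That fit is therefore not a test of the same 9 sequences. In fry, which asks whether the members move one way without comparing them with other miRNAs, the list was lower (adjusted p = 0.000653). Its median log2 fold change was -0.20, and 6.11% of 10000 random lists of 9 other miRNAs, not matched on abundance, had a median as low. Adjusted over the list alone, 4 fell, the fourth being miR857-3p (-0.39, SE 0.12). The abundant guide strand miR398b/c-3p was at 67784 ± 2935 CPM in controls and 66812 ± 1847 with epiBL (SD, n = 3 each), a log2 fold change of -0.02 (SE 0.10) that turned positive under DESeq2-type size factors.

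Of 13 miRNAs linked to sulfate, phosphate and nitrogen supply, 2 rose and 2 fell, and 2 rose and 4 fell adjusted over the list alone. Both that rose were miR395 members, and those that fell were miR399d-3p and miR169h-n-5p. miR827-3p, which acts on phosphate transport, had a log2 fold change of 0.13 (SE 0.10) and did not pass. The list as a whole did not differ (camera, adjusted p = 0.983), its median being 0.06 and its mean -0.10.

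The list of organ growth and meristem miRNAs had a median log2 fold change of 0.16 over 22 members, of which 1 rose (miR170/miR171a-5p), 21 did not pass and 0 passed adjusted over the list alone. camera gave an adjusted p of 0.118, which became 0.0143 without control replicate 2 and 0.0463 without epiBL replicate 2, but 0.653 without control replicate 1 and 0.255 without epiBL replicate 3. With an estimated correlation the adjusted p was 0.733. Of 13 age and phase change miRNAs, miR156g-5p alone rose, over all miRNAs and adjusted over the list alone, and miR157a-c-5p had a log2 fold change of -0.04 (SE 0.10). Of 15 miRNAs of auxin signalling targets, 0 passed over all miRNAs tested in edgeR's test, and 2 rose and 3 fell adjusted over the list alone. They included miR393a/b-5p, which targets auxin receptors (0.29, SE 0.10), miR393a-3p (-0.32, SE 0.11) and miR167a-3p (-0.35, SE 0.12). The list holds both arms of a precursor, so a fall need not be of the arm that acts on the targets. miR167a/b-5p, the other arm at MIR167a, had 0.02 (SE 0.12). Of 7 miRNAs of small RNA machinery targets, miR168b-3p fell, and 1 rose and 1 fell adjusted over the list alone, while miR403-3p, which targets ARGONAUTE2, had 0.30 (SE 0.14). Of 11 triggers of secondary siRNAs, 0 passed either way, with the sequence labelled miR161-3p at 0.01 (SE 0.10). It is annotated as miR161.2 and lies at 17825731-17825751 on chromosome 1, plus strand. That is in the 5′ part of its precursor (17825685-17825857), so the 3p label is doubtful. Of 3 miRNAs of defence receptor targets, 0 passed either way, with miR472-5p at -0.37 (SE 0.19) and miR472-3p at 0.16 (SE 0.14). The conserved families held 4 of the risers and 6 of the fallers among 79 miRNAs. The list labelled as restricted to Arabidopsis or its relatives is every remaining family, without a check of each. It held 0 and 2 among 69. Adjusted over each list alone these were 4 and 8, and 0 and 1. None of these lists differed from the other miRNAs in camera, with adjusted p of 0.271 for age and phase change and at least 0.949 for the others apart from organ growth.

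**Figure D3:**
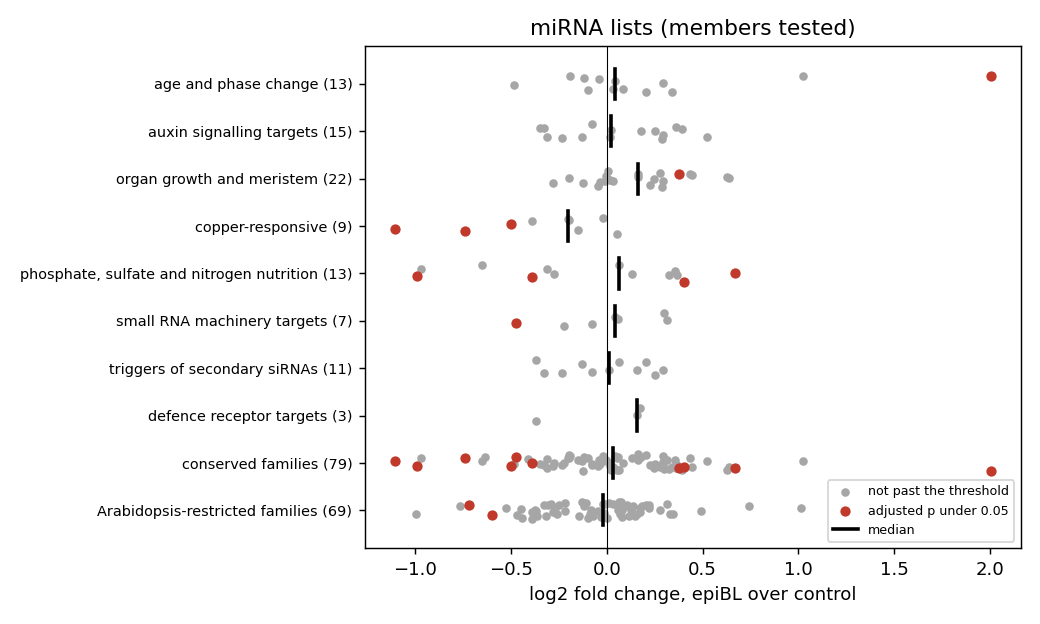
Log2 fold changes (epiBL over control) of the tested members of 10 miRNA lists, with the number tested in brackets. Each point is a miRNA, red points are past an adjusted p of 0.05, black bars are medians, and the copper-responsive list has 8 of 9 members below 0.

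Arm use was compared at 45 pairs of sequences labelled 5p and 3p. The miR161 sequences may not come from opposite arms, and some pairs set an arm pooled over several loci, such as miR393a/b-5p, against the arm of a single locus. At MIR398a, the 5p arm fell against the 3p arm by 1.14 on the log2 scale (SE 0.19, limma adjusted p = 0.00833): the 5p arm had a log2 fold change of -1.11 and the 3p arm of 0.05. The reads counted as miR398a-3p amounted to only 0.0280% ± 0.00151 of those of miR398b/c-3p in controls and 0.0297% ± 0.00222 with epiBL (SD, n = 3 each), and the sequences differ by 1 base (G21T, miR398b/c-3p first, counted from 1 at the 5′ end). The next pair, miR393a/b-5p against miR393a-3p, had a difference of 0.62 (SE 0.16, limma adjusted p = 0.0731). Without epiBL replicate 2 no pair passed, and without control replicate 1 or 2 the number was 2.

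The authors' deposited table gives a p-value for the same comparison, and 42 sequences had one under 0.05 in it, 20 higher and 22 lower. Benjamini-Hochberg adjustment of the p-values of the authors' deposited table over 294 sequences left 12, the same 12 as above. Across the 148 miRNAs, which are not independent replicates, the log2 fold changes of the authors' deposited table and of the refit had a Pearson r of 0.9997.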

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

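The removal of a GC trend, thinning of counts, total-count scaling of the lists and leaving out libraries for the totals were chosen after seeing the data. The 12 calls became 22 with a replicate block and 20 in DESeq2, both holding all 12, 7 of 85 when summed per family, 26 at an adjusted p under 0.1 and 35 at an unadjusted p under 0.05. They ranged from 5 to 25 when 1 library was left out, 5 without control replicate 2 or epiBL replicate 3, 7 without control replicate 3 and 25 without epiBL replicate 2. The cause of these changes was not tested, except that sums per family and thresholds change what is counted. Under the other scalings and filters, limma-trend, GC removal and thinning there were 12 to 17, of which 10 to 12 were among the 12. miR156g-5p, miR398a-5p, miR397a-5p, miR395a/d/e-3p and miR841b-5p passed in all 16 alternatives that test single miRNAs, and the other 7 calls did not. miR156g-5p ranged from 1.88 to 2.14. The replicate numbers did not pair the libraries: correlations of deviations were -0.14, 0.12 and -0.13, and 2 of 6 libraries correlated best with their own number. The block left 1 list called and gave 2 arm ratios, not 1.

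The number of lists called was 0 with an estimated correlation (copper-responsive adjusted p = 0.153) and 0 with 1 value per family (0.158), and 1 to 2 when 1 library was left out. The value per family is a sum that abundant members can dominate, so it does not test the same sequences. The correlation estimated for the copper-responsive list, 0.000865, was under the preset 0.01, so a higher correlation did not cost it the call. What else differs between the camera fits with preset and estimated correlation was not examined. The copper-responsive list stayed called in fry (0.000653), with the replicate block (0.00424), RLE factors (0.00236) and total counts (0.00169), and with each library left out (0.000728 to 0.00645). Arm ratios past the threshold numbered 0 to 2 when 1 library was left out, 0 without epiBL replicate 2. The cause was not tested. Results that had not passed and changed sign were these. miR398b/c-3p was 0.0049 under RLE factors. miR161-3p was -0.13 under total counts and -0.0153 under upper-quartile factors, and miR158a-3p was -0.0590 under total counts. miR159a-3p was 0.0040 in DESeq2, 0.0228 under RLE factors, 0.0140 with 10 counts in every sample of a group, 0.0163 with the GC trend removed and 0.0117 when thinned. With 1 library left out, log2 fold changes ranged from -0.0774 to 0.0103 for miR157a-c-5p, -0.0499 to 0.0166 for miR398b/c-3p, -0.0167 to 0.0829 for miR161-3p and -0.10 to 0.12 for miR159a-3p. Lists whose direction changed had adjusted p of 0.816 (auxin and triggers, 1 value per family), 0.965 (nutrition, fry), 0.95 (nutrition, total counts), 0.952 (machinery, replicate block) and 0.473 (machinery, 1 value per family). With 1 library left out these ranged from 0.451 to 0.995 for auxin, 0.785 to 0.998 for nutrition and defence, 0.771 to 0.998 for machinery and triggers, and 0.321 to 0.994 for conserved and restricted families. Among single miRNAs and uncalled lists, 444 other values kept direction and side of the threshold, 33 lost it and 21 gained it. Depth limits the rarest miRNAs, since 3 counts are 1.46 CPM in epiBL replicate 3.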

Other observations

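All tests of explanations here were chosen after the result was seen, except the draw of lists matched on GC content. Summed per family, an alternative fixed before the data were examined, 7 of 85 families passed in edgeR's test. miR395 (log2 fold change 0.51, SE 0.10), miR170 (0.40, SE 0.12), miR861 (0.38, SE 0.11) and miR2111 (0.37, SE 0.11), a family induced by phosphate shortage, rose, while miR169 (-0.81, SE 0.19), miR863 (-0.54, SE 0.15) and miR857 (-0.37, SE 0.11) fell. The miR170 sum is mostly the called miR170/miR171a-5p (mean 86.8 CPM, against 11.5 for miR170-3p), a sequence that also matches MIR171a. The miR171 sum, which leaves that sequence out, did not pass (0.26, edgeR adjusted p = 0.11). None of the families of the other called miRNAs passed: miR156 (0.07, adjusted p = 0.84), miR398 (0.0041, 0.986), miR397 (-0.19, 0.23), miR841 (-0.02, 0.981), miR408 (-0.19, 0.23), miR168 (0.04, 0.937) and miR399 (-0.02, 0.981). So the calls of miR156g-5p, miR398a-5p, miR397a-5p, miR841b-5p, miR408-5p, miR168b-3p and miR399d-3p did not appear at family level. A sum adds all arms and loci, and each of these sequences was scarce beside another of its family. Mean CPM were 20.1 for miR156g-5p against 3878 for miR156a-f-5p, and 52.6 for miR398a-5p against 67298 for miR398b/c-3p. The least uneven was miR841b-5p, with 188 against 1049 for miR841a-5p. The sums could therefore show little of these calls and decide nothing about them. The 3 miR2111 sequences had log2 fold changes of 0.33 to 0.37 and none passed alone. Within the miR399 family, miR399a-3p (-0.27, SE 0.09), miR399f-3p (-0.31, SE 0.10) and miR399d-3p had values below 0, and miR399b/c-3p had 0.06 (SE 0.10), smaller in size than the median shift of -0.13 under total-count scaling, so no direction is given for it.

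Several calls concerned a scarce sequence 1 base away from a more abundant one. Such a neighbour was present for 5 of the 12 called miRNAs and for 12 of the 136 others (Fisher's exact test, two-sided p = 0.00531, with related sequences not independent). miR841b-5p was 22.9% ± 1.46 of miR841a-5p in controls and 13.2% ± 0.740 with epiBL, and miR397a-5p was 2.07% ± 0.0484 of miR397b-5p in controls and 1.43% ± 0.0965 with epiBL (SD, n = 3 each). miR395a/d/e-3p was 39.2% ± 3.28 of miR395b/c/f-3p, which itself rose, in controls and 47.3% ± 4.96 with epiBL, and miR399d-3p was 7.98% ± 0.284 of miR399a-3p in controls and 7.34% ± 0.465 with epiBL (SD, n = 3 each), the log2 fold changes being -0.39 and -0.27.

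miR156g-5p rose 4.01-fold while its neighbour miR156a-f-5p did not pass. If errors in reads of miR156a-f-5p had caused this, the same base change at the same position (T1C) would be expected to raise miR158b-3p against miR158a-3p by 0.73 on the log2 scale, and the ratio changed by 0.0702 (SE 0.0892). Removing a trend with GC content left the log2 fold change at 2.00 (SE 0.20). A smooth trend fitted over all tested miRNAs cannot follow a change in a single sequence, so this fit decides nothing. No biological explanation was tested, and the other arm and the primary transcript of MIR156g were not analysed here. Trimming, end variants and variants of the plant line were not tested either, and the error test rests on 1 pair.

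The miR398a arm ratio may owe its change to the 3p arm being read from elsewhere. The share of miR398a-3p in miR398b/c-3p counts did not differ between the 6 libraries beyond counting error (chi-square p = 0.94), and it changed by 0.09 on the log2 scale. Errors of the abundant neighbour would give this. So would a genuine miR398a-3p that stayed level, since miR398b/c-3p was level too (-0.02). At a mean of 19.4 CPM for miR398a-3p, small differences would also be missed, so the share does not tell the 2 apart. Of 45 arm pairs, 1 passed. A change of arm use at MIR398a alone remains open, since no count of miR398a-3p free of those reads was at hand. The fall of miR398a-5p itself does not depend on that ratio.

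The mean of the copper-responsive list relative to the other miRNAs of the same library differed by -0.36 on the log2 scale (SE 0.03), lower in every epiBL than in every control library. This restates the call, since camera already compares the list with the other miRNAs, and is no separate test of scaling. Of 10000 random lists matched on GC content, 6.65% had a median as low, above the 5% set beforehand, and of unmatched lists 6.11%. Matching did not move the drawn median (0.02 in both), so this draw decides nothing about GC content, a reading made after its value was seen. A median this low was not rare among lists of 9 drawn from all other tested miRNAs. The draws were not matched on abundance or standard error, so they do not give its rate for miRNAs measured as precisely. The 6 members not past the threshold had a median of -0.17, against -0.20 for the whole list, and a camera p of 0.137. Leaving members out by their result weakens any call, so this does not show whether the call rests on the 3 that passed. A response to epiBL and the copper supply of the cultures were not told apart by any test here.

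Whether the supply of precursors changed was examined by comparing both arms. In some pairs, such as miR156a-f-5p with miR156f-3p, an arm pooled over several loci was set against that of a single locus, which does not measure a single precursor. Across 45 pairs, which are not independent replicates, the fold changes of the 5p and 3p arms had a Pearson r of 0.229 (permutation p = 0.133) and a Spearman rho of 0.256 (permutation p = 0.0876), and r was 0.259 without the 2 pairs farthest from the median. In 30 pairs with both arms above 20 CPM r was 0.07. This neither shows nor excludes a common change of both arms.

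The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. For miRNAs past the threshold, 1 split, the real one, gave as many as 12, and the highest other gave 1. For lists of any kind, 5 splits gave at least the 1 list of the real one, and the highest other gave 3. For the copper-responsive list alone, the unadjusted camera p was 0.00013 in the real split and 0.0129 to 0.424 in the others. In the other splits that called a list it was at least 0.126, so the lists called there were different ones. For arm ratios, 1 split gave as many as 1, and the highest other gave 0.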
